A study of Homo sapiens and Mus musculus with 30 samples.

How the data were processed

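The position and strength of ribose methylation on ribosomal RNA (rRNA) were measured by RiboMeth-seq. In this assay total RNA is broken by alkali, fragments of a narrow size class are ligated to linkers and sequenced, and read ends are counted at every nucleotide. A 2′-O-methyl group protects the bond on its 3′ side, so a methylated nucleotide shows fewer read ends than its neighbours. Per the labels, total RNA came from mouse brain tissue, mouse embryonic stem cells and human pluripotent cells with their differentiated derivatives, and libraries were sequenced on an Ion Proton instrument. The aligner, the counting program and their versions are not given in the sources used here. The labels state that each tissue, line or condition was processed as biological triplicates, and the 30 samples held 93 libraries, 51 human and 42 mouse. Each sample had 3 libraries except undifferentiated H9, which had 6.

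The files deposited by the authors gave 5′ ends, 3′ ends and their sum as raw counts of read ends at every rRNA position of each library, with no scaling between libraries. The deposited methylation score is a fraction from 0 to 1, although per the file headers it is called a percentage. Recomputation from the counts showed how the authors made it: 1 minus the read-end count at a position over the weighted mean of the 6 positions on each side, with weights from 1 next to the position to 0.5 at the sixth, and negative values set to 0. The recomputed and the deposited fraction differed by at most 2.92e-10 over 9951 values. The score depends on the evenness of the neighbours and is not an absolute stoichiometry. The rRNA sequences were spelled out in the files, with lengths in human of 1869 nucleotides for 18S, 5069 for 28S and 154 for 5.8S rRNA, and in mouse of 1871, 4731 and 156. No genome build was involved, and positions are counted from 1 at the 5′ end of each rRNA.

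A catalogue of 107 known methylation sites was written from general knowledge of the field before the data were examined, with 42 sites in 18S, 63 in 28S and 2 in 5.8S rRNA, together with the tests, the groups of sites, the rule for naming sites and most alternatives. Sites keep the numbering of published snoRNA target tables, so that Um in a name stands for a methylated uridine and the digits for its number there. Each site was placed on the human sequence by its base and the score pattern, and on the mouse sequence by alignment. The 18S and 5.8S sites needed no shift. The design had foreseen 1 shift of numbering, but the 28S sites needed several, of 9 nucleotides for 2 sites, 12 for 20, 13 for 4, 21 for 17, 22 for 2 and 30 for 18. In 6 human files the 5.8S sequence lacked its first base, and its positions were moved by 1. All 107 sites could be placed on the catalogue's base in both species. The base was a condition of the placing, so this match does not check the numbering. A site was tested in a species if its mean score over all samples was at least 0.2 and the mean read-end count of its neighbours was at least 50 in every sample. This kept 106 sites in mouse and 105 in human. The sites left out were 18S Um1668, with a mean score of 0.00275 in human and 0 in mouse, and 18S Um354 in human, with a mean score of 0.163. The mean was taken over samples that differ, and 18S Um354 was at 0 in undifferentiated H9 but at 0.745 in mature neurons. The minimum thus removed a site that changes, and its values are given apart, from fits with no minimum.

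Depth ranged from 2077453 to 42703107 read ends per human library and from 1575991 to 42210167 per mouse library. The neighbours of a tested site carried on average at least 145 read ends per position in each human library and 65.6 in each mouse library. The median counting error of a score was 0.00561 in human and 0.00468 in mouse. The median SD between libraries of a sample was 0.0165 and 0.0124, which is 2.93 and 2.64 times as large. Errors are given as the spread between libraries or samples and not as counting error. Read ends are amplified without molecular identifiers, and counting errors cover counting only. The score at all positions outside the catalogue, a background for the assay, averaged between 0.136 and 0.213 per human library and between 0.121 and 0.177 per mouse library.

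Scores were compared with limma (3.58.1, in R 4.3.3) using a trended variance prior and Benjamini-Hochberg adjustment at 0.05 over the tested sites of a comparison. The cortex series was fitted as a slope over the 7 ordered stages with all 21 libraries, and again as a test of any difference between stages. P0 and adult brain were compared with 1 mean per sample and brain region as block, and regions were compared with age in the model. Endoderm, mesoderm and pluripotent cells were compared with 1 mean per sample and the cell line as block. The H9 neural series was compared with its libraries as the units. SNORD52 knock-out and overexpression clones were compared with the 3 unedited pluripotent lines, with 1 mean per sample. Where libraries were the units and samples had their own means, the p-values measure differences against the spread of triplicates from 1 line or tissue. The slope over cortex stages is an exception, as its spread also holds departures of stage means from a straight line. There libraries of 1 stage count as separate points. The slope over cortex stages was also tested by exact permutation of the 5040 orders of the stage means. Correlations across sites used 100000 permutations, two-sided, with the caveat that sites are not independent replicates. Groups of sites were compared by Fisher's exact test, with 144 tests adjusted together.

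Named sites always include 28S Um3904. For each comparison the rule added up to 10 rising and 10 falling sites with the largest change among those past the threshold and with the same sign in every pair, clone or library. If fewer than 5 passed, the 5 sites with the smallest p were added and called not past the test. The guide RNA of a site, a C/D box snoRNA, is given as background from general knowledge and was not checked against a database.

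The alternatives chosen in advance were no minimum on the score, a read-end minimum of 200, an arcsine scale, a variance prior without a trend, a score from 2 positions on each side, edgeR (4.0.16) on the read ends with the neighbours as offset, fits without the block, the cortex samples of 1 library number, H9 alone as the unedited control and leaving out each sample. The alternatives added after the data were seen were leaving out single libraries, libraries as units, comparisons of regions within 1 library number, E12.5 in place of E11, libraries of the same indexes, and a scaling. The scaling divided each score by the upper quartile of its library over the tested sites, because the general level of scores differed between libraries. The file names carry library numbers, read here as batches. E12.5 to P0 cortex shared 1 number, E11 cortex and the other P0 regions another, and all adult tissue a further one. Germ layers, neural stages and SNORD52 clones differed from their controls in library number, so batch and group cannot be told apart there. The exceptions are late precursors and mature neurons, which shared a number.

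The columns of each library are headed by an index sequence. There are 6 indexes, used in 2 sets of 3, and each sample carried 1 set except undifferentiated H9, which carried both. To see whether the index pairs libraries of different samples, the deviations of each library from its sample mean were correlated over the tested sites. In all 61 human and 46 mouse pairs of samples with the same indexes, each of the 3 correlations between libraries of the same index was over 0.1, the lowest being 0.12, and each library correlated best with its own index. For late precursors and mature neurons they were between 0.818 and 0.891. In mouse, where the order of the indexes varies between files, libraries of the same column but another index had a median correlation of -0.352, so the index and not the column pairs them. The labels do not say what libraries of the same index share. After this check the index was used as a block, with libraries as units, in the cortex trend, in H9 endoderm and mesoderm and in the neural series, and the SNORD52 clones were set against the undifferentiated H9 libraries of their indexes with 1 mean per sample. The blocked fits of 3 against 3 libraries have 2 residual degrees of freedom per site and lean on the variance prior. The SNORD52 fits against H9 libraries of the same indexes have 1 H9 mean as control and take their spread from the clones.

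Each test was run on a single simulated set of scores with 30 changed sites, 10 at each size of change. The noise was drawn independently for each site, with no shift of the general level, library number or index. The figures therefore do not give error rates for the real data, where such shifts occur. At a change of 0.1 limma recovered 70% of the changed sites in the cortex trend, 60% for P0 against adult, 20% between regions, 90% for endoderm, 80% for mesoderm, 100% for mature neurons and 70% for the knock-out. No simulated site was called in the wrong direction. Among 75 unchanged sites limma made 4 false calls for late precursors and 3 for mature neurons, and among 76 it made 2 for P0 against adult. In the other comparisons it made at most 2. The files were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and Biopython 1.88, and plots were drawn with matplotlib 3.10.9. The mouse embryonic stem cells have no comparison group, and their values stand with the other observations.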

Results

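RiboMeth-seq scores of rRNA 2′-O-methylation were collected from 14 mouse samples with 42 libraries and 16 human samples with 51 libraries. The mouse samples were cortex at E11, E12.5, E14, E15.5, E17, P0 (birth) and adult, olfactory bulb, cerebellum and hippocampus at P0 and adult, and embryonic stem cells. The human samples were 3 pluripotent lines, the embryonic stem cell lines H9 and HUES4 and the induced pluripotent line KOLF2, each undifferentiated and after directed differentiation to endoderm and to mesoderm. H9 was also followed through early neural precursors, late neural precursors and mature neurons, and was edited to give 2 clones without SNORD52 and 2 clones overexpressing it. Depth ranged from 2077453 to 42703107 read ends per human library, with a median of 19910426, and from 1575991 to 42210167 per mouse library, with a median of 17774274. Per the labels the libraries of a sample are biological triplicates, except that undifferentiated H9 has 6 libraries. A score of 0 stands for no detectable protection and a score of 1 for no read ends at the site.

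The general level of scores differed between libraries. The median score over the tested sites was 0.846 ± 0.0165 (SD, n = 3 libraries) in E11 cortex and between 0.964 and 0.983 in the other cortex samples. It was 0.882 ± 0.0485 in adult cerebellum and 0.903 ± 0.00146 in P0 hippocampus. Among the human samples it was 0.933 in H9, 0.937 in HUES4 and 0.950 in KOLF2, between 0.896 and 0.906 in endoderm, between 0.890 and 0.910 in mesoderm, and 0.901 and 0.904 in the SNORD52 overexpression clones. The main counts of rising and falling sites below are therefore also given after each score was divided by the upper quartile of its library. This scaling was chosen after the data were seen.

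Scores also varied with the index, the short sequence that marks a library in a sequencing run. The libraries carried 6 indexes in 2 sets of 3, and libraries of the same index deviated together from their sample means in 107 of 107 pairs of samples with the same indexes. E12.5 to P0 cortex, undifferentiated HUES4 and KOLF2, late precursors and mature neurons carried index set 1. Undifferentiated H9 carried both sets, and all other samples carried set 2, with the germ layers of all lines among them. Comparisons between libraries of the same indexes, chosen after the data were seen, are therefore given beside the others. The largest difference between the sets within undifferentiated H9 was at 28S Um3904, with 0.706 ± 0.111 (SD, n = 3 libraries) in set 1 and 0.943 ± 0.0538 in set 2, and this 0.237 did not pass after adjustment (adjusted p = 0.327). There limma called 0 of 105 sites between the sets, with 9 at an unadjusted p below 0.05.

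The mouse cortex series asked how rRNA methylation moves as the cortex matures, and the 3 steepest gains, at 18S Um354, 5.8S Um14 and 18S Gm436, started from low scores. In 18S rRNA, Um354 (position 356 of the mouse RNA) had a score of 0 in each of the 3 E11 libraries, 0.141 ± 0.148 (SD, n = 3) at E12.5, 0.770 ± 0.0493 at P0 and 0.980 ± 0.0037 in the adult, a slope of 0.162 ± 0.0118 (SE) per stage. In 5.8S rRNA, Um14 stood at 0.136 ± 0.0508 at E11, 0.0024 ± 0.00416 at E12.5, 0.667 ± 0.12 at P0 and 0.919 ± 0.00626 in the adult. In 18S rRNA, Gm436, a target of SNORD100, rose from 0.169 ± 0.0816 to 0.832 ± 0.0207 between E11 and the adult. Gm867, a target of SNORD98, rose from 0.418 ± 0.0271 to 0.926 ± 0.00357, and Gm1447 from 0.452 ± 0.103 to 0.907 ± 0.0212. In 28S rRNA, Gm2411 rose from 0.516 to 0.910, Gm3923 from 0.540 to 0.919, Gm4020 from 0.479 to 0.822 and Am4541 from 0.618 to 0.980, and 18S Um1442 rose from 0.599 to 0.985. The opposite course was seen at 28S Gm4593, the target of SNORD78 (position 4276), which held 0.657 ± 0.0147 at E11 and 0.699 ± 0.00626 at P0 and was at 0 in all 3 adult libraries.

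Of 106 tested sites, 65 rose and 1 fell along the 7 stages by limma. By rRNA, 24 of 41 sites in 18S, 39 of 63 in 28S and both sites in 5.8S rose. By base, 13 of 34 methylated A, 15 of 20 U, 17 of 23 C and 20 of 29 G rose, and the lower count at A did not pass Fisher's exact test after adjustment (p = 0.000619, adjusted p = 0.0688). After the scaling 39 rose and 18 fell, so the share of rising calls went from 98.5% to 68.4%. All 39 rising sites were among the 65, and 4 of the 65 were called in the opposite direction. Without E11, whose median score was the lowest of the 7 stages, 29 sites rose and 24 fell, 5 of them against their direction in the full series, and without 1 E11 library (library 3) the number of calls was 42. Among E12.5 to P0, which share 1 library number, 46 sites rose and 0 fell, and 41 of these were among the 65. The 10 rising sites named above rose within that batch and after the scaling as well. For 28S Gm4593 the within-batch slope was -0.0105 and not called, the slope without the adult was 0.00801, and the call rests on the adult. 28S Um3904 was at 0.839 ± 0.0442 at E11 and between 0.958 and 0.976 from E12.5 on, and its slope of 0.0133 ± 0.00479 (adjusted p = 0.0227) was not called after the scaling and was -0.000699 without E11. In an exact permutation of the stage order, 26 sites passed an adjusted p of 0.05, all rising, and after the scaling 32 passed, of which 25 rose. Of the sites named above, 28S Gm4020 (adjusted exact p = 0.0812), 28S Gm4593 (0.407) and 28S Um3904 (0.4) did not pass this test, and the smallest p these orders can give is 0.000397. Any difference between stages was called at 103 sites, and at 34 within the E12.5 to P0 batch. With the index as a term in the slope fit 96 sites rose and 3 fell (55 and 25 after the scaling), and all 66 calls were kept.

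**Figure D1:**
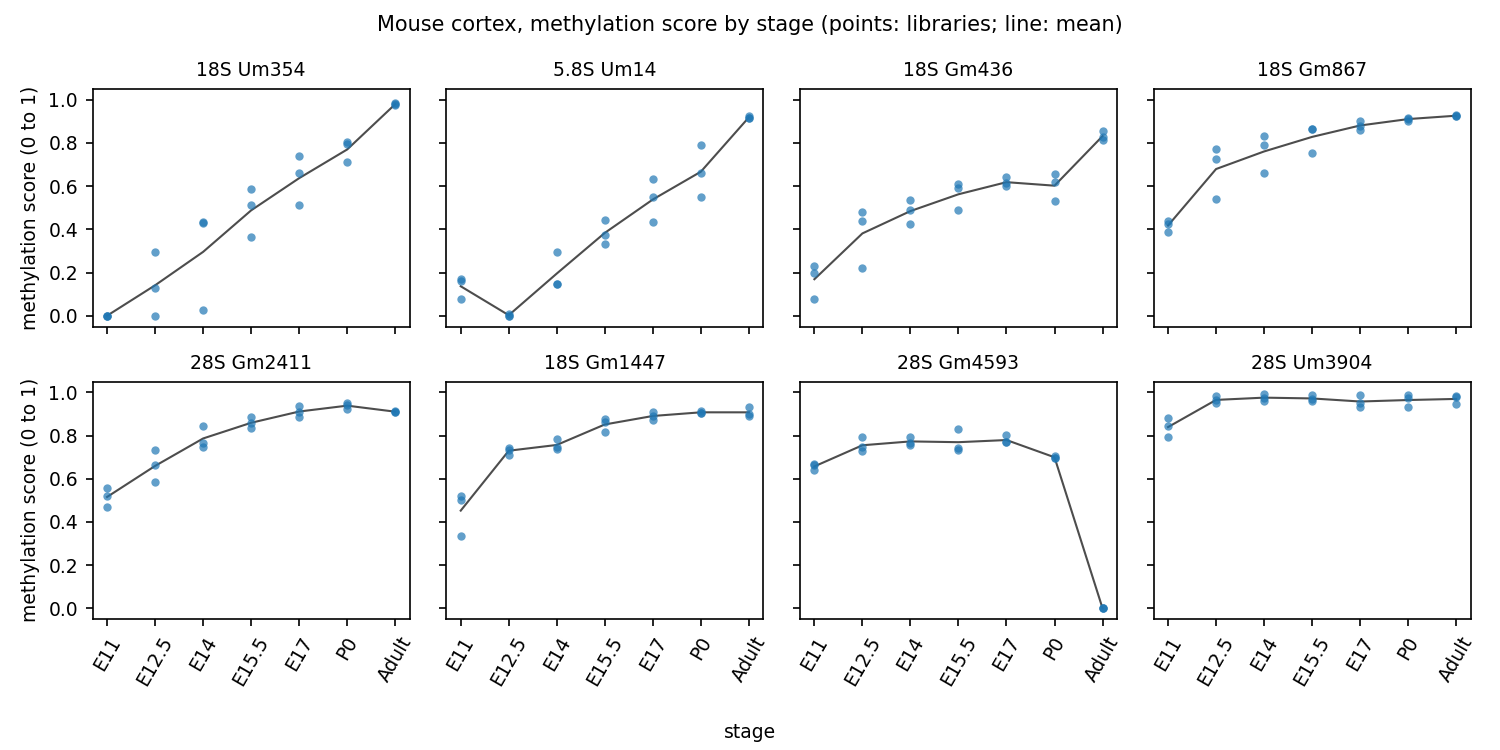
RiboMeth-seq score (fraction, vertical axis) of named sites in each library of mouse cortex over the 7 ordered stages (horizontal axis, not to scale in time), with lines through the means of 3 libraries. 18S Um354 goes from 0 at E11 to 0.980 in the adult, and 28S Gm4593 is at 0 in the adult.

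Comparison of P0 with adult in cortex, hippocampus, cerebellum and olfactory bulb asked whether the changes after birth are shared across the brain, and 5 sites moved in the same direction in 4 of 4 regions. 28S Gm4593 had a mean of 0.552 ± 0.115 (SD, n = 4 regions) at P0 and 0.0767 ± 0.0926 in the adult, a difference of -0.475 ± 0.0997 (SE, adjusted p = 0.000639). It fell by 0.699 in cortex, 0.581 in hippocampus, 0.370 in cerebellum and 0.249 in olfactory bulb. 18S Am576, a target of SNORD93, fell from 0.884 ± 0.0467 to 0.622 ± 0.0788, and 28S Gm4607, a target of SNORD121, from 0.910 ± 0.0102 to 0.736 ± 0.0686. 18S Um354 rose from 0.752 ± 0.0531 to 0.964 ± 0.0211 and 5.8S Um14 from 0.724 ± 0.0761 to 0.910 ± 0.0237. 28S Um3904, at 0.937 ± 0.0358 and 0.925 ± 0.0565, was not called (adjusted p = 0.954).

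These were the 2 rising and 3 falling calls among 106 sites by limma with region as block, and 11 sites had an unadjusted p below 0.05. After the scaling 3 rose and 4 fell. Without the block there were 6 calls, 5 of them shared, and with each library as its own unit 14. The count is sensitive to the variance model and to single regions: there were 0 calls with no minimum on the mean score, 1 with a prior without a trend, 1 without cortex, 2 without cerebellum, 2 without olfactory bulb and 34 without hippocampus. P0 cortex carries other indexes than the adult samples and the other P0 regions. Without cortex, where the indexes match, 28S Gm4593 was the 1 call and the other 4 sites missed the threshold. All P0 samples differ in library number from the adult samples, so age and batch cannot be told apart in this comparison.

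**Figure D2:**
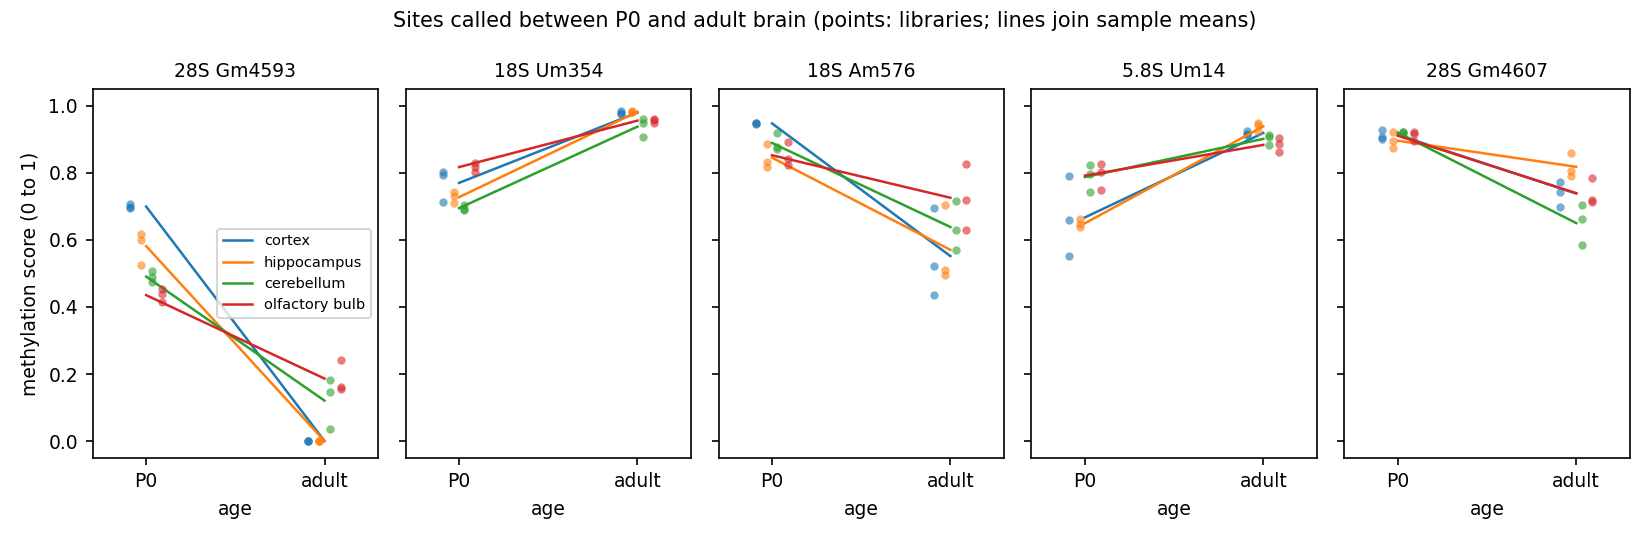
RiboMeth-seq score (fraction, vertical axis) of the 5 sites called between P0 and adult, with 1 point per library (3 for each brain region and age) and lines that join the means of a region at both ages. 28S Gm4593 falls in all 4 regions, from a mean of 0.552 to 0.0767.

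Sites that differed between brain regions at both ages included 18S Gm436 and 28S Cm3820, which were chosen after their values were seen. Within the adult samples, which share a library number, 18S Gm436 had a score of 0.832 ± 0.0207 (SD, n = 3 libraries) in cortex, 0.859 ± 0.02 in hippocampus, 0.455 ± 0.121 in olfactory bulb and 0.427 ± 0.137 in cerebellum (adjusted p = 0.0055). At P0 it was 0.376 ± 0.0744 in hippocampus, 0.576 ± 0.0442 in cerebellum and 0.617 ± 0.0291 in olfactory bulb (adjusted p = 0.0099). 28S Cm3820 ranged from 0.734 ± 0.0981 in adult cerebellum to 0.971 ± 0.0082 in adult cortex, and at P0 it was 0.753 ± 0.0382 in hippocampus against 0.967 in the other 2 regions of that batch. Both sites stayed past the threshold at both ages after the scaling. The order of regions was not kept between ages, as 18S Gm436 was highest in adult hippocampus and lowest in P0 hippocampus. The low values of 28S Cm3820 lay in adult cerebellum and P0 hippocampus, where the median score was also low (0.882 and 0.903). The scaling equalises upper quartiles only, so a difference in level at lower sites can remain.

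The planned comparison of regions over both ages called 0 of 106 sites by limma, with 2 at an unadjusted p below 0.05 (28S Cm2409 and 28S Cm4426), and edgeR also called 0. On simulated data limma recovered 30% of changes of 0.2 and edgeR 0%, so limma has little power with 1 mean per region and age and the edgeR count carries no information. With libraries as units it called 7 sites, and within a batch regions differed at 48 sites in the adult (13 after the scaling) and at 36 sites among 3 regions at P0 (17 after the scaling). Those last tests were chosen after the data were seen. They had no term for the index, although the libraries of each batch carry the same 3 indexes.

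Differentiation of H9, HUES4 and KOLF2 to endoderm asked which sites change on leaving pluripotency. Among the named sites the deepest falls were at 28S Um4197, 18S Gm436 and 18S Cm797. The naming rule asks for the same sign in all 3 lines, so agreement between lines at sites named by their change is not a result. 28S Um4197 (human position 4227) fell from 0.963 ± 0.0109 (SD, n = 3 lines) to 0.659 ± 0.0103, a difference of -0.305 ± 0.0179 (SE, adjusted p = 1.8e-05). 18S Gm436 fell from 0.650 ± 0.0924 to 0.299 ± 0.0225 and 18S Cm797 from 0.884 ± 0.022 to 0.644 ± 0.0435. Smaller falls were found at 28S Gm4588 (0.895 to 0.758), 28S Am2774 (0.856 to 0.721), 18S Um172 (0.877 to 0.746) and 28S Gm4340 (0.963 to 0.842). They were also found at 28S Gm4469 (0.956 to 0.840), 28S Am3809 (0.979 to 0.866) and 28S Cm3820 (0.923 to 0.815). Against this direction 18S Gm867 rose by 0.194 ± 0.0312, 28S Am2388 by 0.136 ± 0.0218 and 28S Am4560 by 0.109 ± 0.0249. The SNORD52 target 28S Um3904 rose from 0.715 ± 0.114 to 0.868 ± 0.0237, by 0.0326 in H9, 0.253 in HUES4 and 0.173 in KOLF2 (adjusted p = 0.00814), and missed the threshold without HUES4 (0.103, adjusted p = 0.0956). This direction did not hold between libraries of the same indexes, which only H9 has: there the site was lower in endoderm, at 0.857 ± 0.047 (SD, n = 3 libraries) against 0.943 ± 0.0538, a difference of -0.0858 ± 0.0153 (SE, adjusted p = 0.0142).

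By limma 4 of 105 sites rose and 45 fell in endoderm, with the cell line as block, and 51 were called without the block. Of the falls, 17 of 40 tested sites lay in 18S and 28 of 63 in 28S rRNA. After the scaling 18 rose and 25 fell, so that the share of rising calls went from 8.16% to 41.9%, and the 25 falls were all among the 45. The 14 named sites kept their call and direction. Among H9 libraries of the same indexes 8 sites rose and 44 fell, and 11 rose and 12 fell after the scaling. Of the 52 unscaled calls 34 were shared with the comparison of 3 lines. In the unscaled fit 28S Gm4469 (adjusted p = 0.0542) and 28S Am4560 (0.00989, adjusted p = 0.713) did not pass. Endoderm and pluripotent libraries never share a library number.

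In mesoderm the deepest falls were at 18S Gm436, from 0.650 ± 0.0924 (SD, n = 3 lines) to 0.299 ± 0.0203, and at 18S Cm797, from 0.884 ± 0.022 to 0.572 ± 0.047. 28S Gm4340 fell to 0.823 ± 0.0525, 28S Gm4588 to 0.762 ± 0.0535, 18S Gm509 to 0.824 ± 0.0195, 18S Am468 to 0.841 ± 0.00933, 28S Am4541 to 0.795 ± 0.0317 and 28S Um4197 to 0.856 ± 0.0262. 18S Cm1272, a target of SNORD66, rose from 0.382 ± 0.0869 to 0.590 ± 0.0297, 18S Gm867 by 0.182 ± 0.0312 (SE), 28S Am4560 by 0.128 ± 0.0249 and 28S Am2388 by 0.123 ± 0.0218. 28S Um3904 had a difference of 0.093 ± 0.0369 and did not pass (adjusted p = 0.0594). It passed with a score from 2 positions on each side, with edgeR, after the scaling and without H9. Among H9 libraries of the same indexes it was lower in mesoderm, by a difference of -0.103 ± 0.0206 (adjusted p = 0.0234).

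In this comparison 4 of 105 sites rose and 52 fell, and 51 were called without the block. After the scaling 16 rose and 15 fell, all 15 among the 52, so the share of rising calls went from 7.14% to 51.6%, and 1 site was called in the opposite direction. Without HUES4 there were 32 calls. The 14 sites named by their change kept their direction and call after the scaling. Among H9 libraries of the same indexes 5 sites rose and 36 fell, 28 of these shared, and 10 rose and 9 fell after the scaling. In the unscaled fit 18S Cm1272 (0.0582, adjusted p = 0.45), 28S Am2388 (0.0767, 0.122) and 28S Am4560 (0.0276, 0.293) did not pass.

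Set directly against each other, mesoderm and endoderm, whose libraries never share a library number, differed most at 28S Um4197, which was higher in mesoderm by 0.198 ± 0.0179 (SE, n = 3 lines, adjusted p = 0.000488), with differences of 0.161 in H9, 0.219 in HUES4 and 0.213 in KOLF2. 28S Am2774 was higher in mesoderm by 0.0895 ± 0.018 and 28S Gm1509 by 0.0468 ± 0.00906, each in 3 of 3 lines (adjusted p = 0.0403). 28S Um3904 had a score of 0.808 ± 0.039 in mesoderm and 0.868 ± 0.0237 in endoderm and was not called (adjusted p = 0.502). By limma 3 sites passed and 10 had an unadjusted p below 0.05. There was 1 call, at 28S Um4197, on an arcsine scale, with 2 neighbours on each side, with edgeR, after the scaling, without the replicate block by cell line and without KOLF2, 0 calls without HUES4 and 7 without H9.

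**Figure D3:**
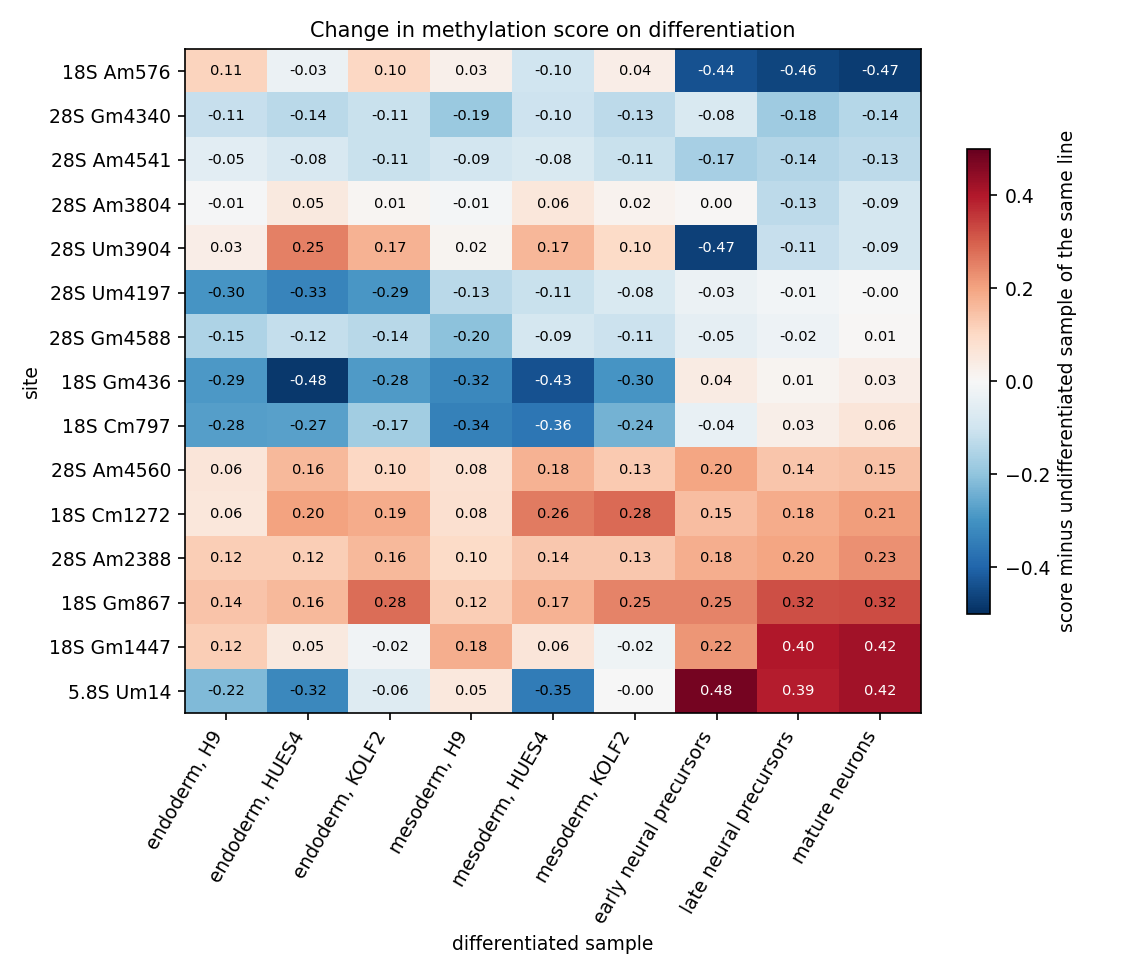
Change in RiboMeth-seq score from the undifferentiated state (difference of fractions, colour and number in each cell) at named sites, in endoderm and mesoderm of each line and in H9 neural stages. The change at 18S Gm436 in endoderm is -0.288 in H9, -0.482 in HUES4 and -0.283 in KOLF2, and at 18S Am576 it is -0.475 in mature neurons.

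Neural differentiation of H9 asked how the profile moves on the path to neurons, and several of the large changes were already present in early precursors. 5.8S Um14 rose from 0.264 ± 0.148 (SD, n = 6 libraries) in undifferentiated cells to 0.744 ± 0.0263 (n = 3) in early precursors, 0.655 ± 0.0334 in late precursors and 0.685 ± 0.0209 in mature neurons. 18S Gm1447 rose from 0.483 ± 0.0613 to 0.705 ± 0.0603, 0.885 ± 0.0014 and 0.903 ± 0.0144, and 18S Gm867 from 0.646 ± 0.0769 to 0.895, 0.967 and 0.970. 28S Am2388 and 18S Um428, both targets of SNORD68, stood in mature neurons at 0.894 ± 0.0156 and 0.922 ± 0.00946, above 0.665 ± 0.0591 and 0.751 ± 0.0278 in undifferentiated cells. 18S Am576 fell from 0.735 ± 0.0315 to 0.299 ± 0.139, 0.277 ± 0.0182 and 0.260 ± 0.0163. 18S Um354 was left out by the minimum on the score averaged over all human samples, and its values were looked at after the data were seen. It was at 0 in all 6 undifferentiated libraries, 0.373 ± 0.0672 in early precursors, 0.682 ± 0.0578 in late precursors and 0.745 ± 0.0264 in mature neurons. With no minimum it rose in each of these stages (adjusted p = 7.8e-11 for mature neurons), and also against undifferentiated libraries of the same indexes.

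Further falls were found at 28S Am4541, a target of SNORD63, from 0.851 ± 0.00717 to 0.686 ± 0.0342 in early precursors and 0.718 ± 0.0112 in mature neurons, and at 28S Gm4340, a target of SNORD60, from 0.949 ± 0.017 to 0.873 ± 0.0239 and 0.807 ± 0.0163. The SNORD52 target 28S Um3904 fell from 0.825 ± 0.152 to 0.359 ± 0.0772 in early precursors, a difference of -0.466 ± 0.0832 (SE, adjusted p = 0.000429), lower in 3 of 3 libraries. It was at 0.711 ± 0.132 in late precursors (adjusted p = 0.301) and at 0.738 ± 0.126 in mature neurons (adjusted p = 0.413), neither of which passed. Against undifferentiated libraries of the same indexes the differences were -0.584, 0.00455 and 0.0317 in the 3 stages, and early precursors alone passed.

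By limma 51 of 105 sites differed among the 4 stages. In early precursors 21 rose and 12 fell, in late precursors 31 and 10, and in mature neurons 36 and 8. In mature neurons 17 of 40 sites in 18S and 18 of 63 in 28S rRNA rose, and 11 of 19 methylated U rose and 0 fell. After the scaling the split was 24 and 15 in early precursors (rising share 63.6% before and 61.5% after). It was 27 and 15 in late precursors (75.6% before and 64.3% after) and 30 and 15 in mature neurons (81.8% before and 66.7% after). A change of at least 0.1 that also exceeded the range of the 3 undifferentiated lines was seen at 11 sites in early precursors, 16 in late precursors and 16 in mature neurons. Against undifferentiated libraries of the same indexes, with the index as block, 22 rose and 15 fell in early precursors, 29 and 10 in late precursors and 30 and 9 in mature neurons. Of these calls 28, 35 and 37 were shared with the comparison without the index. After the scaling 26 rose and 12 fell in early precursors, 31 and 20 in late precursors and 31 and 18 in mature neurons.

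Late precursors and mature neurons share a library number and the same 3 indexes. Without a block limma and edgeR called 0 sites between them, with 1 at an unadjusted p below 0.05 in limma, 28S Am3809. With the libraries paired by index as a block, chosen after the data were seen, 16 sites were higher in mature neurons and 0 lower by limma, and edgeR called 18. 28S Am3809 was higher by 0.0579 ± 0.00799 (SE, 3 of 3 pairs, adjusted p = 2.17e-06), 18S Cm174 by 0.0485, 28S Gm4607 by 0.0424 and 18S Cm797 by 0.0309. After the scaling 8 were higher and 4 lower. 28S Um3904 was higher by 0.0272 ± 0.0163, in 3 of 3 pairs, and did not pass (adjusted p = 0.225). The other stages differ from undifferentiated H9 in library number.

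SNORD52 guides methylation of 28S Um3904, which is position 3925 of the human and 3584 of the mouse 28S sequence, within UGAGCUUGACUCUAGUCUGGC in both species. In the 6 libraries of the SNORD52 knock-out clones its score was between 0 and 0.0905, with 377 to 2268 read ends at the site, and in the other 45 human libraries between 0.295 and 0.977. Clone 1 had a mean of 0.0302 ± 0.0523 (SD, n = 3 libraries) and clone 2 of 0.0158 ± 0.0156. Both overexpression clones stood at 0.893 ± 0.034 and 0.895 ± 0.0424. Unedited H9 had 0.825 ± 0.152 (n = 6), with the difference between index sets given above, HUES4 0.598 ± 0.139 and KOLF2 0.721 ± 0.214 (n = 3 each). In the 42 mouse libraries the site was between 0.773 and 0.994.

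**Figure D4:**
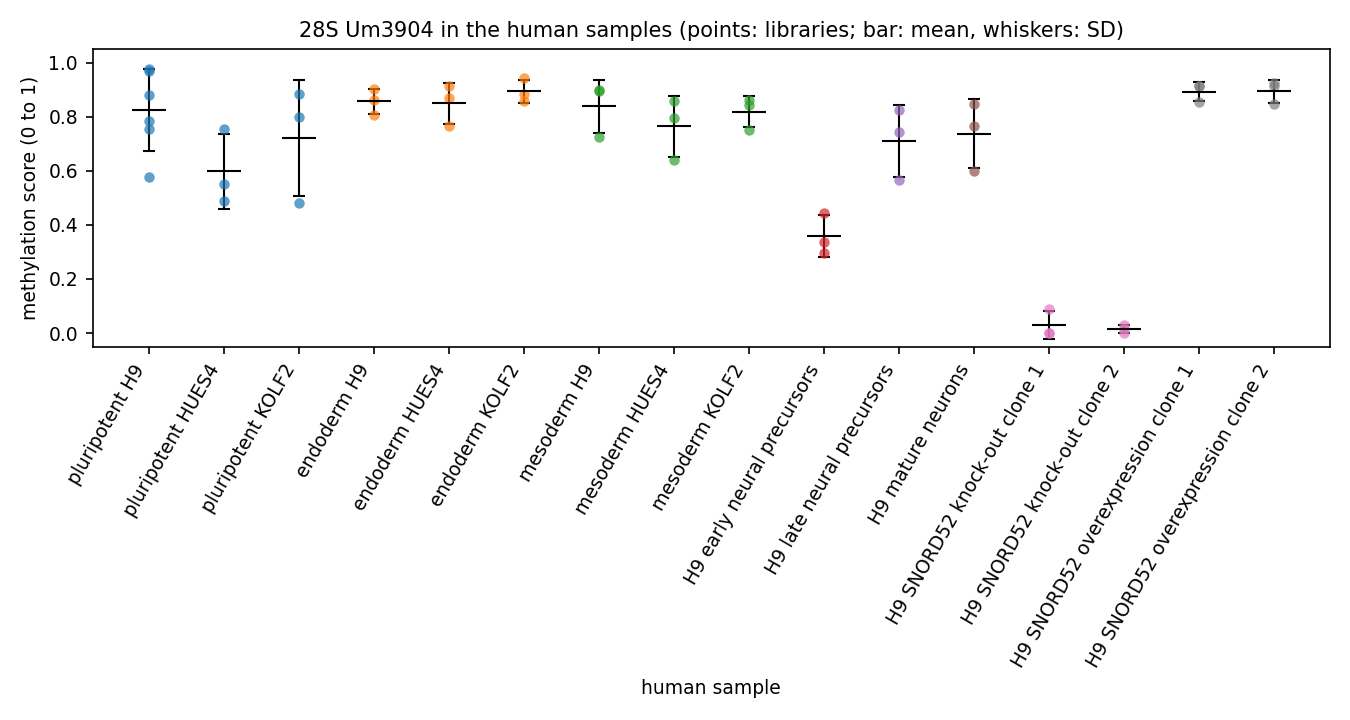
RiboMeth-seq score of 28S Um3904 (fraction) in each of the 51 human libraries, grouped by sample, with sample means and whiskers of 1 SD. The 6 knock-out libraries lie between 0 and 0.0905, and all others at 0.295 or above.

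In the knock-out clones 28S Um3904 fell by 0.692 ± 0.0701 (SE) against the 3 unedited lines, in 2 of 2 clones (adjusted p = 7.55e-06). Against the 3 H9 libraries of the same indexes the difference was -0.920. The clones also differed from the unedited lines at sites other than this target. 28S Am1310 fell from 0.665 ± 0.19 (SD, n = 3 lines) to 0.260 ± 0.00894 (n = 2 clones), 18S Am576 from 0.781 ± 0.0822 to 0.391 ± 0.0478, 28S Am4541 from 0.888 ± 0.0351 to 0.671 ± 0.00827, 28S Am2774 from 0.856 to 0.693 and 28S Am1511 from 0.917 to 0.760. 5.8S Um14 rose from 0.226 ± 0.146 to 0.628 ± 0.00324, 18S Gm867 from 0.613 ± 0.0588 to 0.920 ± 0.00223, 18S Cm1272 from 0.382 ± 0.0869 to 0.639 ± 0.0229, 18S Gm1447 from 0.566 to 0.766, and 28S Am4560 and 28S Am2388 by 0.220 and 0.201. The clones derive from H9, and part of these differences lay between the unedited lines. Against H9 alone the change was -0.185 at 28S Am1310 (H9 at 0.445 ± 0.0975, SD, n = 6 libraries), -0.0887 at 28S Am1511 (H9 at 0.848 ± 0.14, an SD larger than the change) and 0.161 at 18S Cm1272 (H9 at 0.478 ± 0.045), more than 1.5 times smaller than against the 3 lines. Against the H9 libraries of the same indexes it was -0.210, -0.019 and 0.138, and 28S Am1511 did not pass (adjusted p = 0.456). 18S Um354, left out by the minimum score, was at 0.378 ± 0.0416 in clone 1 and 0.294 ± 0.0839 in clone 2 (SD, n = 3 libraries) and at 0 in all undifferentiated H9 and overexpression libraries, and it rose in the knock-out with no minimum (adjusted p = 0.000231).

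Of 105 sites, 17 rose and 20 fell in the knock-out by limma, and after the scaling 23 rose and 18 fell (45.9% and 56.1% rising). Among methylated A, 4 of 34 rose and 11 fell. With 1 clone the count was 16 without clone 1 and 18 without clone 2, where the lone clone is assumed to vary like the other groups. All knock-out libraries share a library number that no other human sample has.

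In the overexpression clones the target site 28S Um3904 was higher than in the unedited lines by 0.179 ± 0.0701 (SE), at the edge of the threshold (adjusted p = 0.0477), and this direction did not hold between libraries of the same indexes. Against the 3 H9 libraries with the clones' indexes it was lower, at 0.894 against 0.943, a difference of -0.0493 that did not pass (adjusted p = 0.0967). HUES4 and KOLF2 carry the other index set. Against H9 alone with all 6 libraries, the parent line, it was 0.0692, less than the SD of 0.152 between the 6 H9 libraries. That fit kept the call (adjusted p = 0.0175), but with 1 H9 sample it takes its spread from the clones. The call was lost with no minimum on the mean score (adjusted p = 0.0809), with a prior without a trend (0.0664), without HUES4 (0.16), without KOLF2 (0.0711) and with either clone alone (0.27 without clone 1 and 0.259 without clone 2). Larger changes lay at 18S Gm436, which fell from 0.650 ± 0.0924 (SD, n = 3 lines) to 0.201 ± 0.0104 (n = 2 clones), and at 28S Gm4340, which fell from 0.963 ± 0.0128 to 0.756 ± 0.0209. Smaller falls were found at 18S Gm509 from 0.945 to 0.808, 28S Cm3820 from 0.923 to 0.787 and 28S Gm4593 from 0.951 to 0.826. 28S Am4560 rose from 0.690 ± 0.0467 to 0.829 ± 0.0131 and 18S Am1031 by 0.0207. By limma 3 sites rose and 46 fell, and after the scaling 15 rose and 30 fell, all 30 among the 46 (6.12% and 33.3% rising). Against the H9 libraries of the same indexes the control is 1 H9 mean, and the spread comes from the clones. Counts of calls from those fits are therefore not given, for overexpression or for the knock-out.

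Directly compared, knock-out and overexpression clones differed most at 28S Um3904, which was lower in the knock-out by a difference of -0.871 ± 0.0768 (SE, n = 2 clones each, adjusted p = 1.22e-06). 18S Cm174 was higher in the knock-out, at 0.759 ± 0.0264 (SD) against 0.234 ± 0.00651, as were 18S Gm436 at 0.555 ± 0.023 against 0.201 ± 0.0104, 5.8S Um14 at 0.628 ± 0.00324 against 0.333 ± 0.0507 and 18S Gm867 at 0.920 against 0.662. 18S Am576 was lower at 0.391 ± 0.0478 against 0.798 ± 0.0169, as was 28S Am1310 at 0.260 against 0.594. By limma 44 sites were higher and 7 lower in the knock-out, and 31 and 17 after the scaling (86.3% and 64.6% higher). The clones share no library number, so the edit and the batch cannot be told apart for these other sites.

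Across species, the change from undifferentiated H9 to mature neurons was compared site by site with the change from E11 to adult mouse cortex. Over 105 sites Spearman's rho was 0.481 (permutation p = 1e-05, the smallest that 100000 permutations can give), and 81 sites had the same sign. After the scaling, chosen after the data were seen, rho was 0.493 (permutation p = 1e-05) with 72 sites of the same sign. The general score was low in E11, so the unscaled count of signs may in part follow that level. Low scores have more room to rise in both species, and permuting sites does not remove this. 18S Gm867, 18S Gm1447, 28S Gm4020 and 5.8S Um14 had higher scores in both mature states, while 28S Am4541 was lower in human neurons and higher in adult mouse cortex. Sites are not independent replicates. 18S Um354, not among the 105, was also higher in both mature states. With E12.5 in place of E11, chosen after the data were seen, rho was 0.150 (permutation p = 0.125) with 46 sites of the same sign, but E12.5 and adult cortex differ in index set. Against undifferentiated libraries of the same indexes as mature neurons, rho was 0.542 with E11 to adult, which share indexes, and 0.511 with E12.5 to P0, which share indexes and a library number (permutation p = 1e-05 each, with 86 and 87 sites of the same sign). These 2 were also chosen after the data were seen.

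Groups of sites by rRNA, base, part of the molecule or level were tested for an excess of calls in each comparison, and 0 of 144 Fisher's exact tests passed after adjustment, with 9 at an unadjusted p below 0.05. In mature neurons, sites between 0.5 and 0.9 had 20 rises and 6 falls among 42 members, and sites at 0.9 or more had 15 rises and 2 falls among 60 (adjusted p = 0.0688 for calls in either direction). Tests of rises alone and of falls alone also gave 0 after adjustment, with 20 and 9 at an unadjusted p below 0.05.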

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

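The interaction tests and Dixon's ratio follow rules fixed in advance, and the minimum score of 0.75 for positions outside the catalogue was chosen after the data were seen.

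The change from P0 to adult differed between brain regions at 71 of 106 sites by a limma interaction test with libraries as units and no term for the index. The widest ranges of the difference were 0.6449 at 18S Gm436, where the adult minus P0 difference was 0.483 in hippocampus, 0.23 in cortex, -0.149 in cerebellum and -0.162 in olfactory bulb, 0.5484 at 28S Cm2409 and 0.4505 at 28S Gm4593. P0 cortex carries another library number and other indexes than the other P0 regions, and median scores were low in P0 hippocampus and adult cerebellum, so the interaction and the level of single samples cannot be told apart.

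The change to mesoderm differed between H9, HUES4 and KOLF2 at 19 of 105 sites. The range was 0.4532 at 18S Cm174 (-0.168 in HUES4 and 0.285 in KOLF2), 0.4028 at 5.8S Um14 and 0.401 at 28S Am3846. The change to endoderm differed between lines at 1 site, 18S Cm174, with a range of 0.7547, from -0.26 in H9 to 0.495 in KOLF2. Undifferentiated HUES4 and KOLF2 carry other indexes than their germ layers, and H9 carries both sets. H9 mesoderm also has another library number (28) than mesoderm of HUES4 and KOLF2 (33), while endoderm of all lines has 32. The undifferentiated lines differ in library number as well. Line, index and library number therefore cannot be told apart here.

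Among the 6 undifferentiated H9 libraries, 13 of 105 sites had 1 library far from the other 5 by Dixon's ratio, against 5.25 that chance gives at the 5% level. Library 6 was the lowest at 9 of these sites and library 3 at 4. Each of the 6 libraries carries another index, and libraries of the same index deviated together across samples.

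Some rRNA positions outside the catalogue were protected in every library of their species. The lowest score in any library was 0.9307 at human 28S G 2363 and 0.9265 at human 28S G 3792. In mouse it was 0.9608 at 28S G 2122, 0.9222 at 28S G 3451, 0.841 at 28S C 4718 and 0.7715 at 28S U 4719. The mouse and human G lie next to the same catalogue site, 28S Am2350, or 7 nucleotides from 28S Am3764, and the mouse C and U lie near the 3′ end of the RNA.

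In 45 libraries of 14 human samples other small RNAs were counted as well. In U2, a spliceosomal RNA, the lowest score in any library was 0.7697 at G 12, 0.8401 at G 25 and 0.8529 at A 30. It was 0.8842 at G 37 of U5A and 0.7775 at A 47 of U6. No position of 5S, 7SL, U1, U12, U3A, U4 or U8 reached a score of 0.75 in every one of these libraries.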

How the results depend on the processing

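Tests chosen after the data were seen are the scaling by the upper quartile, single libraries left out, libraries as units, samples of 1 library number for the regions, E12.5 in place of E11, and libraries of the same indexes; the others, with the cortex samples of 1 library number among them, were planned. Of 3253 values of named sites under an alternative, 3070 kept their direction and their side of the threshold, 168 lost the call, 7 gained it and 8 reversed. Most named sites were picked from the same data by their size and sign, and many alternatives leave out 1 sample or library. These counts therefore do not measure how robust the results are. In the cortex trend 28S Gm4593 had a slope of 0.0044 over days after conception without the adult and 0.00801 over stages without the adult, and 28S Um3904 had -0.0019 among E12.5 to P0 of 1 library number and -0.000699 without E11. Leaving out 1 stage or library gave slopes from -0.114 to 0.00801 at 28S Gm4593 and from -0.000699 to 0.0175 at 28S Um3904, whose calls rest on the adult and on E11. The other 4 reversals came with libraries of the same indexes: 28S Um3904 was -0.0858 in endoderm and -0.103 in mesoderm, with the index as block, and -0.0493 in overexpression, where 28S Am1511 was 0.00796. Leaving out 1 line or clone had given 0.103 to 0.213, 0.0563 to 0.132 and 0.121 to 0.234 at 28S Um3904, and -0.165 to -0.107 at 28S Am1511, so leaving out samples did not show the part of the index.

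The number of calls moved by more than 1.5 times in these cases, where the cause was not tested unless given. A minimum read-end count of 200, which leaves fewer sites to test, gave 37 calls in the cortex trend and 54 in the test between cortex stages, and E12.5 to P0 of 1 library number gave 34 in the latter. P0 against adult gave 0 calls with no minimum on the mean score, 1 with eBayes without a trend and 14 with each library its own unit. The differences between brain regions gave 7 with each library its own unit, 48 among adult and 36 among P0 samples of 1 library number. Mesoderm against pluripotent cells gave 31 after the scaling by the upper quartile. Mesoderm against endoderm gave 1 on the arcsine scale, 1 with 2 positions on each side, 1 with edgeR, 1 after the scaling and 1 with no replicate block by cell line. The size rule for mature neurons gave 29 sites at 0.05 and 6 at 0.2. The human and mouse changes had a rho of 0.150 with E12.5 in place of E11, 0.542 with libraries of the same indexes and 0.511 with these and E12.5 to P0.

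Leaving out 1 sample, line, clone or library gave 42 to 97 calls in the cortex trend, 82 to 103 in the test between cortex stages, 1 to 34 for P0 against adult and 0 for regions. It gave 33 to 73 for endoderm, 32 to 72 for mesoderm, 0 to 7 for mesoderm against endoderm and 45 to 57 for the neural series, with 29 to 37 in early precursors, 28 to 46 in late precursors, 30 to 50 in mature neurons and 0 between the last 2. It gave 16 to 48 for the knock-out, 37 to 71 for overexpression and 34 to 61 between them. Pairing knock-out and overexpression clones by number as a replicate block gave 73 calls, but the numbers do not pair the clones (r = -0.0195 between their differences over 105 sites).

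The indexes pair libraries across samples. Mature neurons against late precursors went from 0 to 16 calls with the index as replicate block, where edgeR called 18. The other counts with the index as block moved by no more than 1.5 times. They were 99 in the cortex trend, 63 for the neural series, 37 for early precursors and 39 for late precursors. For mature neurons the count was 39, for endoderm 52 and for mesoderm 41. Germ layers in HUES4 and KOLF2 have no libraries of the same indexes as their controls.

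The median SD between libraries was 2.93 times the median counting error in human and 2.64 times in mouse. The 95th percentile of the counting error was 0.0175 in human and 0.0167 in mouse, against 0.103 and 0.104 for the SD between libraries. The largest counting errors, 0.0568 and 0.0658, exceed the median SD of 0.0165 and 0.0124. At sites and in libraries with few read ends depth may thus add to the spread.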

Other observations

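The tests with scaled scores or with the library index, the shares of sites that held within 1 library number or after scaling, and the relations of the SNORD52 clones with differentiation were chosen after the results were seen; the regroupings of samples were planned.

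Mouse embryonic stem cells, which belong to no comparison above, had low scores at several sites that rose along the cortex series. 18S Um354 was at 0 in all 3 libraries, 5.8S Um14 at 0.368 ± 0.0503 (SD, n = 3), 18S Gm436 at 0.360 ± 0.0826 and 18S Gm867 at 0.451 ± 0.0397. 28S Gm4593 was at 0.672 ± 0.00574, 18S Am576 at 0.905 ± 0.00521 and 28S Um3904 at 0.911 ± 0.0324. Their libraries carry a number that no brain sample has, and no test was made.

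The rise along the cortex series may in part follow the low general score of the E11 libraries or a batch. Against a batch of the E11 and adult samples as the whole cause, 41 of the 65 rising sites (0.631) also rose among E12.5 to P0 of 1 library number, where 46 of all 106 sites rose and 0 fell. After the scaling 39 of the 65 (0.6) still rose. The scaling equalises upper quartiles only, and a difference in level at lower sites can remain. In library 1 of E11 the median was 0.851 and the upper quartile 0.910, against 0.981 and 0.992 in library 1 of P0. The scaling therefore cannot decide whether the library-wide score level is the whole cause. With the library index as block 96 of all 106 sites rose, with all of the 65 (a share of 1) among them. So many sites rose that this share does not single out the 65. That sites still rose with the index in the fit argues against the index as the whole cause. The block does not remove the low general score of E11. Batch stays open for the sites that did not rise within that library number, and score level for all 65. Of the 65, 4 were called as falling after the scaling. Of 100 orders of the stages, 18 gave at least the 66 calls of the real one, and the highest other order gave 91. Chance therefore cannot be excluded for the count. Whether the low E11 scores account for the order with more calls than the real one was not tested. Developmental age stays open as an explanation.

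The falls in endoderm and mesoderm could reflect the lower general score of the differentiated libraries. After the scaling 0.556 of the 45 fallen sites were still called down in endoderm and 0.288 of 52 in mesoderm. The scaling equalises upper quartiles only, and a difference in level at lower sites can remain, so these shares do not decide it. Among H9 libraries of the same indexes 0.711 of the falls in endoderm and 0.519 of those in mesoderm were called down with unscaled scores. This argues against the library index as the whole cause of these unscaled falls, and the index stays open for the other sites. After the scaling the same fits called 12 sites down in endoderm and 9 in mesoderm. Library numbers differ between pluripotent and differentiated samples, and batch and germ layer cannot be told apart.

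The changes in the SNORD52 knock-out clones resembled those of neural differentiation. With separate controls, HUES4 and KOLF2 for the clones and H9 for the neurons, Spearman's rho across sites was 0.412 for mature neurons, which argues against the shared H9 control as the whole cause. Without 28S Um3904 it was 0.397 over 104 sites (permutation p = 2e-05, adjusted p = 2.67e-05). HUES4 and KOLF2 carry other indexes than the clones. With the clones and the neurons each set against the undifferentiated H9 libraries of their own indexes, rho was 0.627. Without 28S Um3904 it was 0.646 (permutation p = 1e-05 each, the smallest these permutations can give). Those H9 libraries are of 1 sample and share a library number, so a deviation of that sample enters both changes. These values argue against the library index and against the target site as the whole cause. No comparison here removed the index and the shared H9 sample at once. Low scores also have more room to rise in both, which permuting sites does not remove. With early precursors rho was 0.616 (permutation p = 1e-05), where the clones and the precursors share an index set that their controls lack in full or in part, so the index stays open there. Partial differentiation of the clones, a state of the starting culture and a batch effect of the knock-out libraries may each account for it, and these were not tested.

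For the overexpression clones rho was -0.00369 with mature neurons (permutation p = 0.97) and 0.494 with H9 endoderm (permutation p = 1e-05, the smallest these permutations can give). The indexes differ from the controls here as well. Median scores were 0.901 and 0.904 in these clones and 0.896 in H9 endoderm. They were higher in the controls, at 0.937 in HUES4, 0.950 in KOLF2 and 0.933 in H9. A drop in level on both sides can give a positive rho, and this was not tested. Each against H9 libraries of its own indexes, overexpression and mature neurons had a rho of 0.207 (permutation p = 0.0355, unadjusted). Except for the values by index, these were 4 relations in 1 family, and sites are not independent.

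Other splits of the samples were refitted for each comparison. For P0 against adult, 3 of 35 splits gave as many calls, with 5 for the real split and 6 for the highest other, so chance cannot be excluded. Among the 8 splits that part both ages of every region, the highest other gave 0, but 8 splits are too few for a share under 0.05. For the H9 neural series 1 of 100 regroupings, the real one, gave as many, with 51 calls against 10 for the highest other, and a chance assignment of single libraries can be excluded. The regroupings mix libraries of different samples and library numbers, so they say nothing about differences between samples or batches as such. The 10 splits of each germ layer comparison are too few for a share under 0.05. The real split gave 49 calls for endoderm and the highest other 0, 56 and 0 for mesoderm, and 3 and 1 for mesoderm against endoderm.

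After the scaling, sites at a level of 0.5 to 0.9 held more rises than other sites in the cortex trend (21 of 31, adjusted p = 0.00619) and in mature neurons (20 of 42, adjusted p = 0.0278) by Fisher's exact test. Sites at 0.9 or more held fewer (17 of 71, adjusted p = 0.0147, and 9 of 60, adjusted p = 0.0233). A score near 1 has little room to rise, so the groups differ in what can be called. With unscaled scores 0 of these tests passed, with 20 at an unadjusted p below 0.05.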
